A study of Mus musculus with 9 samples.

How the data were processed

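Small RNA was sequenced from back skin of adult female C57BL/6 mice, a common inbred laboratory strain, aged 6 months. A punch of 8 mm diameter was used to wound the back under anesthesia. The 9 samples form 3 groups of 3: skin removed at wounding (day 0), wound-edge skin at day 7, and skin of a diabetic mouse model. The labels of the diabetic group disagree with each other. Its titles carry T7, the matching columns of the table carry T0, and its treatment text describes skin removed at wounding. The day of collection of the diabetic group was therefore left open, and the group was compared with both others. The table's T columns were matched to the diabetic samples by the letter T and the replicate number. The labels speak of 9 mice, but they do not say whether a day 0 and a day 7 sample came from the same animal, nor how diabetes was induced.

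The authors deposited 1 table with a whole-number read count and a TPM value for each miRNA and sample, per the file headers. The deposited read counts were not normalized, and totals ranged from 2537167 to 5453539 per sample. The deposited TPM values equal the CPM of a library's total count, which was tested on the table, so they carry no length term. The submitters' processing notes name Bowtie with no version, DESeq version 3.0.3 and the mouse build mm9, with no role given for any of them. Adapter trimming, mismatch settings, the treatment of reads with several matches and the use of strand are not given in the sources used here. The table has 1129 rows, of which 30 are miRNAs predicted from reads and absent from miRBase names. These 30 rows hold 0.00196% of all counts.

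Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM library scaling and 1 fit over all 9 samples. The filter on low counts was filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 447 miRNAs. The rows left out hold 0.0217% of all counts. A miRNA was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM values are counts scaled to a common library size by the TMM-scaled totals, with a prior count of 2 on the log scale. Because TMM sets a typical miRNA to no change and no spike-in was used here, fold changes are relative to the other miRNAs and say nothing of absolute amounts.

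A set of 18 miRNA lists with 218 entries, for cell types and processes of skin wounds, was fixed before the data were examined, and 212 entries were in the table. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 18 lists. The test was repeated with an estimated correlation and with fry. The miRNAs named in the text were also set by a rule written beforehand. They are the 8 largest increases and 8 largest decreases with an adjusted p under 0.05, a mean CPM of at least 10 and no overlap between the 3 and 3 libraries. To these come 20 skin, wound and muscle miRNAs whatever their test, and for each list the 2 to 4 most abundant members that passed. Any other miRNA named was chosen after its values were seen, and the text says so. Shares of counts were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.

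The tests were run on simulated counts before the real fits. Counts for 447 miRNAs were drawn from the real means, spreads and library sizes, with 100 miRNAs changed 2-fold and 100 changed 4-fold. For day 7 against day 0, 66% of the 2-fold and 97% of the 4-fold changes were recovered, and 6 of 247 unchanged miRNAs were called. For the diabetic group against day 0 the shares were 58% and 92%, with 2 of 247 called. For the diabetic group against day 7 they were 70% and 96%, with 6 of 247 called. In each comparison camera called the 1 list raised 2-fold and none of 17 unchanged lists. The simulated miRNAs were drawn independently of each other, so this check does not cover correlation between the members of a list. The real spread between replicates was 27.8% (common biological coefficient of variation).

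Replicates of a group differed far beyond counting noise, with a chi-square of 178 to 1497 per degree of freedom, so no library appeared to be deposited more than once within its group. Libraries of different groups were not compared by this test. The labels number the replicates 1 to 3 in each group. Deviations from the group means correlated between same-numbered libraries in all 9 pairs, from 0.102 to 0.484, and in each of the 9 pairs the same number gave the highest correlation. By the criterion fixed for this check, every pair over 0.1, the numbers pair the samples, on the data alone. The check rests largely on miR-122-5p and its opposite-strand partner row: without these rows 6 of the 9 pairs exceeded 0.1 and in 5 of the 9 the same number gave the highest correlation. A fit with the replicate number as a block was an alternative.

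Hairpin genes and their neighbours were taken by name from RefSeq, and 1078 of the 1099 miRBase-named rows matched a hairpin gene there. Host genes, strands and hairpin sequences were taken from GENCODE M21. Its build differs from that of the submitters' notes, so no coordinates are given. Of all rows, 15 pairs were equal within 5% in all 9 libraries at a mean count of at least 20, and 12 of these pairs lie on opposite strands of the same locus. Another pair, miR-486a-3p and miR-486a-5p, holds complementary arms of 1 hairpin. Such rows cannot be told apart here and are reported as uncertain, among them miR-1a-3p with miR-1b-5p and miR-142a-3p with miR-142b. Members of repeated families such as miR-466, miR-467 and miR-669 share sequence and are uncertain too. Alternatives covered the library scaling, the low-count filter, DESeq2 1.42.0, limma on log2(TPM + 1), the samples in the fit, the replicate block, a fold minimum, the 5 most abundant miRNAs and each replicate left out. Alternatives that dropped opposite-strand partner rows (with miR-486a-5p, and also for the share of the 10 most abundant rows), miR-21a-5p, or the libraries numbered 2 were chosen after seeing the data, as was the overlap of the day 7 changes with those of the diabetic group against day 7. Figures were drawn with matplotlib 3.10.9.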

Results

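miRNA read counts were obtained for 9 libraries of mouse back skin in 3 groups of 3: skin removed at wounding (day 0), wound-edge skin at day 7, and skin of a diabetic mouse model titled T7. Library totals were 3185362, 5453539 and 2807482 counts at day 0, 4767089, 3937692 and 2537167 at day 7, and 5322272, 4536661 and 2861130 in the diabetic group, for replicates 1, 2 and 3. Between 667 and 805 rows of the table had at least 1 count in a library. The labels do not settle the day on which the diabetic samples were taken, so for that group a difference in time and the diabetic model cannot be separated. Where the labels do not name separate animals, p-values measure the spread between these samples.

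A single miRNA, miR-21a-5p, an abundant miRNA induced in inflamed and injured tissue, made up 26.4% ± 7.34 of all counts at day 0, 49.6% ± 7.95 at day 7 and 16.6% ± 2.85 in the diabetic group (SD, n = 3 each). All 3 day 7 libraries lay above all libraries of both other groups. The exact two-sided permutation p was 0.1 for day 7 against day 0 and for the diabetic group against day 7, the smallest that 3 against 3 allows, and 0.2 for the diabetic group against day 0. The 10 most abundant rows together took 69.7% ± 3.61 of counts at day 0, 79.3% ± 1.95 at day 7 and 67.2% ± 3.37 in the diabetic group (SD, n = 3 each). Their exact permutation p was 0.1, 0.5 and 0.1 for day 7 against day 0, diabetic against day 0 and diabetic against day 7. These rows include miR-1a-3p and its opposite-strand row miR-1b-5p, which cannot be told apart here. With 1 row of each such pair left out of counts and totals the shares were 70.5% ± 3.93, 79.8% ± 2.42 and 67.4% ± 2.19 (exact permutation p = 0.1, 0.3 and 0.1).

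**Figure D1:**
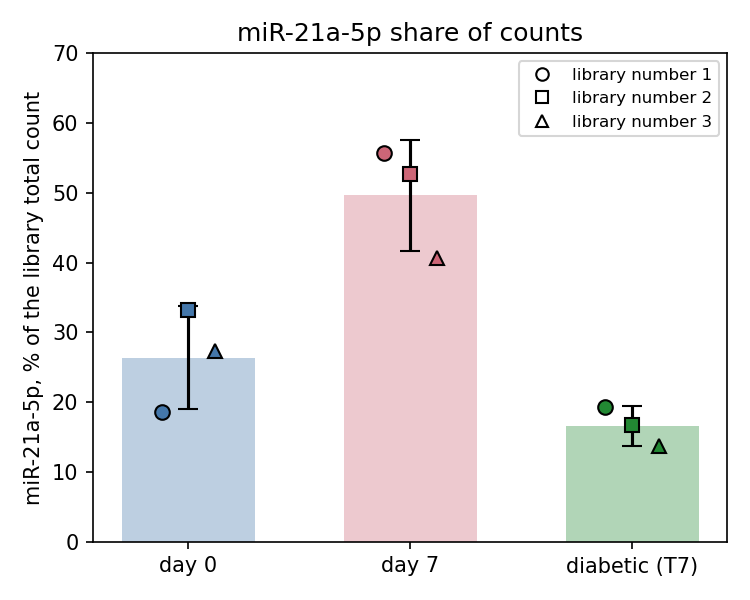
Share of each library's total count taken by miR-21a-5p, in percent, with bars for group means, error bars for the SD (n = 3) and a symbol for each library number. The day 7 libraries lie between 40.6% and 55.6%, above the day 0 libraries (18.6% to 33.2%) and the diabetic libraries (13.7% to 19.4%).

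The first comparison asked which miRNAs differ between the wound edge at day 7 and the skin removed at wounding. The largest increase was in miR-335-3p, from the intron of the imprinted gene Mest, which rose 14.8-fold (log2 fold change 3.89 ± 0.40, SE, n = 3 per group, edgeR adjusted p = 4.17e-04), from 7.64 ± 1.67 to 113 ± 46.5 CPM (mean ± SD). Its partner arm miR-335-5p rose 4.31-fold (2.11 ± 0.36). miR-34c-5p, a member of the p53-induced miR-34 family, rose 3.31-fold (1.73 ± 0.33), and miR-7a-5p rose 3.24-fold (1.70 ± 0.32). The neutrophil and macrophage miRNA miR-223-3p rose 3.19-fold, from 108 ± 25.6 to 345 ± 74.6 CPM, and miR-223-5p rose 3.14-fold. miR-669a-5p, from an intron of Sfmbt2 and sharing sequence with its neighbours, rose 2.90-fold, and miR-342-3p, from an intron of Evl, rose 2.88-fold.

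The decreases that the rule for named miRNAs gave (a mean of at least 10 CPM and no overlap between the groups) were smaller. miR-181c-3p fell by 1.07 on the log2 scale (SE 0.26), miR-193b-3p fell by 1.00, miR-429-3p fell by 0.94 and miR-130a-3p fell by 0.91. miR-199b-5p fell by 0.87, from 1315 ± 57.6 to 718 ± 74.4 CPM, miR-96-5p fell by 0.81, and miR-182-5p fell by 0.79, from 3096 ± 246 to 1787 ± 138 CPM. miR-181c-5p fell by 0.79. Adjusted p-values of these 8 decreases ran from 0.00596 for miR-182-5p to 0.0422 for miR-181c-5p (edgeR, n = 3 per group). Leaving out day 0 replicate 3, day 7 replicate 1 or day 7 replicate 2 each ended the calls of miR-181c-3p, miR-193b-3p, miR-429-3p, miR-130a-3p and miR-181c-5p, with adjusted p-values from 0.0612 to 0.154 (edgeR). Leaving out day 0 replicate 2 ended all of these but miR-429-3p (0.0661 to 0.0912), diabetic replicate 2 ended miR-193b-3p (0.0539), miR-130a-3p (0.0510) and miR-181c-5p (0.0550), and day 0 replicate 1 (miR-193b-3p, 0.0727) and diabetic replicate 1 (miR-181c-5p, 0.0508) ended 1 call each. Scaling by total counts without miR-21a-5p ended the calls of miR-96-5p (0.0521), miR-181c-3p (0.0632) and miR-181c-5p (0.0942), and the fit of only the 2 groups that of miR-193b-3p (0.0552). Of the increases, miR-223-5p lost its call without day 7 replicate 1 (0.0599). A larger decrease outside that rule, with overlapping ranges and named after its value was seen, was that of miR-135b-5p, from 16.6 ± 11.4 to 3.20 ± 0.986 CPM (-2.40 ± 0.61, adjusted p = 0.0281, edgeR). It passed in 16 of 21 alternatives and lost its call without day 0 replicate 2 (0.107) or 3 (0.0844), day 7 replicate 1 (0.114) or 2 (0.0807), or the libraries numbered 2 (0.352).

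Among the miRNAs chosen beforehand, miR-21a-5p rose 2.69-fold at day 7 (1.43 ± 0.33, adjusted p = 0.0178, edgeR), miR-155-5p, which is induced in activated immune cells, rose 2.08-fold, miR-142a-3p of blood cells, which cannot be told apart here from its opposite-strand row miR-142b, rose 2.06-fold and the red-cell miRNA miR-451a rose 2.29-fold. The epidermal miRNA miR-205-5p fell by 0.59 (adjusted p = 0.0499, edgeR). The others did not pass the test. Their log2 fold changes were 0.76 for miR-206-3p, 0.67 for miR-132-3p, 0.50 for miR-1a-3p, 0.41 for miR-146a-5p, 0.32 for miR-126a-3p and 0.26 for miR-17-5p. On the negative side they were -0.51 for miR-133a-3p, -0.40 for miR-199a-3p, -0.37 for miR-143-3p, -0.27 for miR-200c-3p, -0.24 for miR-203-3p, -0.21 for let-7b-5p, -0.04 for miR-210-3p and -0.01 for miR-31-5p. With the replicate number as a block miR-206-3p passed (0.76, adjusted p = 0.0164, edgeR, and 0.0409 or 0.0456 without diabetic replicate 1 or 3), and miR-199a-3p passed without day 0 replicate 1 (0.0335) or diabetic replicate 3 (0.0456). In all, miR-206-3p passed in 6 and miR-199a-3p in 8 of 22 alternatives. With these, 8 of the miRNAs listed as not passing here passed in at least 1 alternative.

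Several of these calls were lost when 1 library was left out, with the sign kept (edgeR adjusted p-values). miR-21a-5p lost its call without day 0 replicate 3 (0.0602), day 7 replicate 1 (0.0931) or day 7 replicate 2 (0.0612), where its log2 fold change was 1.49, 1.23 and 1.31. miR-155-5p lost it without day 0 replicate 2 (0.0879), day 7 replicate 1 (0.0950) or day 7 replicate 2 (0.0578), at 0.79, 0.96 and 1.05. miR-451a lost it without day 0 replicate 2 (0.162) or 3 (0.123), day 7 replicate 1 (0.237) or 2 (0.104), or diabetic replicate 2 (0.0664), at 1.06, 0.98, 0.81, 1.19 and 1.14. miR-205-5p lost it without day 0 replicate 2 (0.115) or 3 (0.174), day 7 replicate 1 (0.142), 2 (0.104) or 3 (0.0507), or diabetic replicate 2 (0.0550), at -0.69 to -0.47. With total-count scaling the calls of miR-142a-3p, miR-155-5p and miR-451a were lost, and those of miR-155-5p and miR-451a also with upper-quartile scaling and with limma. miR-451a lost it too without the 5 most abundant miRNAs and with total counts without miR-21a-5p. In all, miR-451a passed in 11, miR-205-5p in 14, miR-155-5p in 15 and miR-142a-3p in 20 of 22 alternatives, and miR-21a-5p in 16 of 20.

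Of the 7 tested myeloid and lymphoid cell miRNAs, 5 rose and none fell at day 7 (6 rose when adjusted over the list alone), with a median log2 fold change of 1.09 and a camera adjusted p of 2.28e-06. The most abundant was miR-142a-5p, at 497 ± 87.1 CPM at day 0 and 1010 ± 163 CPM at day 7. Of 12 inflammation-induced miRNAs, 6 rose (6 adjusted over the list alone), among them miR-146b-5p (1.07 ± 0.19) and miR-222-3p (0.64 ± 0.17), with a median of 0.84 and a camera adjusted p of 1.00e-04. Of 17 keratinocyte and epithelial miRNAs, 7 fell and 10 did not pass (10 fell adjusted over the list alone), with a median of -0.65 and a camera adjusted p of 9.60e-08. The members that fell include miR-205-5p, miR-200a-3p (-0.66 ± 0.18) and miR-182-5p. Of 7 erythroid miRNAs, miR-451a and miR-144-3p rose (6 rose adjusted over the list alone), with a camera adjusted p of 0.0179. That list holds the opposite-strand rows of miR-486, and its call was lost without such rows (adjusted p = 0.0509), with total-count scaling (0.0654), without day 0 replicate 3 (0.0729) and without day 7 replicate 1 (0.0697). List members are not all separate loci. The erythroid list holds 3 rows of miR-486 and 3 of the miR-144 and miR-451a cluster, and the myeloid list both arms of miR-223 and of miR-142a. Camera with the preset correlation of 0.01 treats such members as nearly independent. With an estimated correlation none of the 4 lists kept its call: adjusted p = 0.115, 0.115, 0.115 and 0.529, in the order given. With total-count scaling their medians were 0.58, 0.29, -1.18 and 0.05. By fry, 6 lists moved, the other two being the nerve and diabetic-wound lists (adjusted p = 0.0337 and 0.0445), and its mixed test, which takes changes in either direction, called 9. Other splits of the same 6 libraries called up to 8 lists, against 4 for the real split.

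Of the list members named there, miR-222-3p passed in 7 of 22 alternatives, miR-144-3p in 11, miR-200a-3p in 17, and miR-142a-5p and miR-146b-5p in 19 each (edgeR adjusted p-values). miR-222-3p lost its call without day 0 replicate 1 (0.0894), 2 (0.107) or 3 (0.117), day 7 replicate 1 (0.169), 2 (0.144) or 3 (0.0591), or diabetic replicate 2 (0.0817). miR-144-3p lost it without day 0 replicate 2 (0.125) or 3 (0.113), day 7 replicate 1 (0.180) or 2 (0.0857), or diabetic replicate 2 (0.0550), and miR-200a-3p without day 0 replicate 2 (0.0684) or 3 (0.113) or day 7 replicate 1 (0.117) or 2 (0.115). With total-count scaling the calls of miR-222-3p, miR-144-3p, miR-142a-5p and miR-146b-5p were lost.

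The other 14 lists had camera adjusted p-values from 0.213 to 0.992 for day 7 against day 0. Median log2 fold changes were -0.10 for striated muscle (mean 0.01), -0.14 for smooth muscle and pericyte, -0.07 for fibroblast and matrix, -0.08 for melanocyte and -0.46 for the miR-31 list. They were 0.29 for endothelial, 0.03 for adipocyte, 0.25 for nerve, 0.04 for let-7, 0.30 for the miR-17/92 clusters, 0.07 for the imprinted Dlk1-Dio3 locus, 0.98 for the miR-34 family, 0.48 for the hypoxia list and 0.41 for miRNAs reported in diabetic wounds. The medians of the endothelial, adipocyte, nerve, let-7, miR-17/92, Dlk1-Dio3, hypoxia and diabetic-wound lists turned negative with total-count scaling. The camera direction was opposite in sign to the median for let-7, Dlk1-Dio3 and striated muscle. In the adipocyte list miR-335-3p and miR-335-5p rose while miR-193b-3p fell.

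In all, 57 of 447 tested miRNAs changed at day 7, 36 higher and 21 lower (edgeR, adjusted p under 0.05), and 30.4% had ranges that did not overlap between the groups, against 10% by chance. Scaling by total counts gave 16 higher and 117 lower, and upper-quartile scaling 26 higher and 34 lower, with the median log2 fold change of all tested miRNAs at -0.46 and -0.12 instead of 0.08. limma on TPM gave 17 higher and 122 lower, and total counts without miR-21a-5p gave 28 higher and 7 lower. The number of calls fell to 27 without day 0 replicate 2, 22 without day 0 replicate 3, 19 without day 7 replicate 1 and 23 without day 7 replicate 2. Without the 3 libraries numbered 2 it was 1, miR-335-3p.

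**Figure D2:**
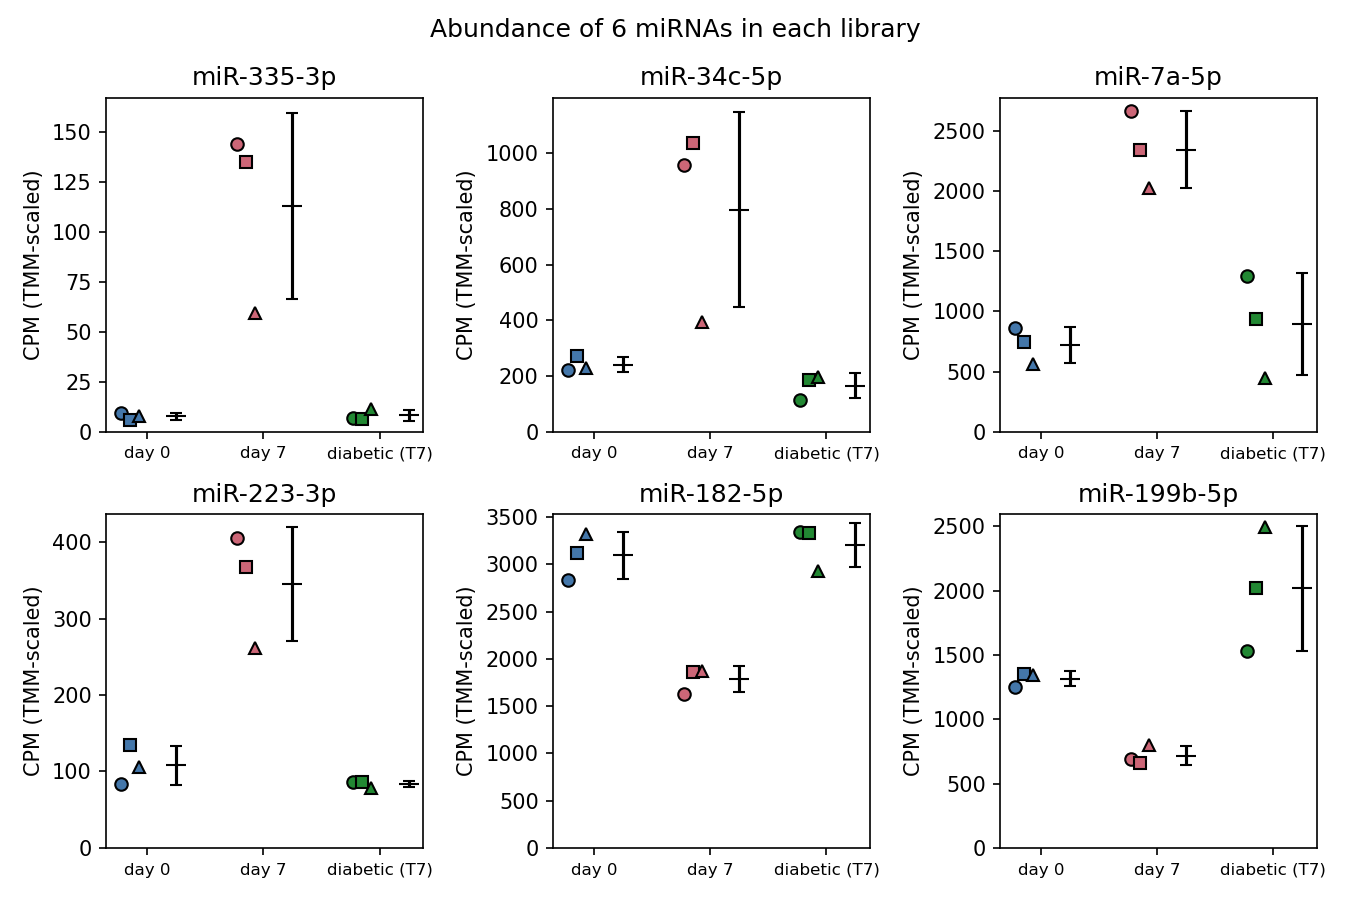
TMM-scaled CPM of 6 miRNAs in each of the 9 libraries, with a symbol for each library number as circle (1), square (2) and triangle (3), and black marks for the group mean and SD (n = 3). miR-335-3p averaged 7.64 CPM at day 0, 113 CPM at day 7 and 8.22 CPM in the diabetic group, while miR-182-5p averaged 3096, 1787 and 3205 CPM.

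The second comparison set the diabetic group against non-diabetic skin at day 0. No miRNA passed the edgeR test (0 of 447), with 40 at an unadjusted p under 0.05, and DESeq2 called 8 and limma on TPM called 1. The smallest adjusted p belonged to miR-342-3p, named after its value was seen: 45.5 ± 2.77 CPM in the diabetic group against 17.3 ± 3.96 CPM at day 0 (log2 fold change 1.39 ± 0.24, adjusted p = 0.0569, edgeR). It passed in the fit with the replicate number as a block, the 1 call of that fit (1.41, adjusted p = 0.0281, edgeR), and in 10 of 22 alternatives in all, where its adjusted p ran from 1.60e-04 to 0.796. miR-21a-5p had a log2 fold change of -0.82 ± 0.32 (adjusted p = 0.529, edgeR) and passed with DESeq2 (adjusted p = 0.0482) and without the low-count filter.

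Other miRNAs chosen beforehand did not pass, and their log2 fold changes in the diabetic group against day 0 lay between -0.37 for miR-223-3p and 0.65 for miR-206-3p. miR-17-5p stood at 0.44 ± 0.21, with all 3 diabetic libraries above all 3 day 0 libraries. The miR-17/92 and paralogous clusters, 14 miRNAs with a median of 0.37, were higher by camera (adjusted p = 0.00290), with 0 members past the test over all miRNAs and 1 adjusted over the list alone. The 2 tested melanocyte miRNAs, miR-211-5p (1.89 ± 0.56) and miR-204-5p (0.50 ± 0.20), named after their values were seen, were higher as a list (adjusted p = 0.0115), with 0 past the test and 2 adjusted over the list alone. The 4 tested miR-34 miRNAs were lower as a list (median -0.73, adjusted p = 0.0115), with 0 past the test and 1 adjusted over the list alone. With an estimated correlation the adjusted p of these 3 lists was 0.484. The directional fry test called 0 lists, and its mixed test called 3, the myeloid and lymphoid (adjusted p = 5.95e-06), fibroblast (0.0156) and let-7 (0.0356) lists. The miR-34 call ended without opposite-strand rows (0.0564) and with a CPM of at least 10 (0.661), which also ended the melanocyte call (0.291). Without day 0 replicate 1 the miR-17/92 and miR-34 calls ended (0.188 each), without day 0 replicate 3 the melanocyte and miR-34 calls (0.0965 each), without diabetic replicate 1 all 3 (0.0772, 0.0839 and 0.0502 for miR-17/92, melanocyte and miR-34), and without diabetic replicate 3 the miR-34 call (0.135). Other splits of these 6 libraries called up to 4 lists, against 3 for the real split. The other 15 lists had camera adjusted p-values from 0.0661 to 0.857 and medians from -0.27 to 0.57. The fibroblast list had a median of 0.04 and a downward camera direction. Ranges did not overlap for 13.9% of miRNAs, against 10% by chance, and the count of calls was 1 without day 0 replicate 1 (miR-135b-5p) and 2 without day 7 replicate 3 (miR-342-3p and miR-34b-3p, all named after their values were seen).

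The third comparison set the diabetic group against the day 7 wound edge. miR-335-3p was 14.0-fold lower in the diabetic group (-3.80 ± 0.39, adjusted p = 4.77e-04, edgeR), at 8.22 ± 2.74 CPM. miR-223-5p was 5.95-fold lower, miR-335-5p 5.94-fold, miR-21a-3p 5.55-fold and miR-34c-5p 4.83-fold lower. miR-21a-5p was 4.74-fold lower (-2.24 ± 0.34, adjusted p = 0.00130, edgeR), miR-223-3p 4.13-fold, and miR-501-3p, from an intron of Clcn5, 3.07-fold lower. On the other side miR-375-3p was 3.70-fold higher (1.89 ± 0.34), miR-199b-5p 2.81-fold, miR-31-3p 2.58-fold and miR-181c-3p 2.55-fold higher. miR-193b-3p was 2.53-fold higher, miR-98-5p of the let-7 family 2.45-fold, miR-345-5p 2.43-fold and miR-130a-3p 2.39-fold. The call of miR-31-3p was lost without day 7 replicate 1 (adjusted p = 0.0703, edgeR) and without diabetic replicate 2 (0.0687), and that of miR-501-3p with total-count scaling.

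Among the miRNAs chosen beforehand, miR-142a-3p (-1.27 ± 0.19), miR-451a (-1.43 ± 0.34) and miR-155-5p (-0.75 ± 0.24, adjusted p = 0.0478, edgeR) were lower in the diabetic group than at day 7. The call of miR-155-5p was lost in 16 of its 22 alternatives, where its adjusted p ran from 0.0375 to 0.768 (edgeR and the other tools). These include the replicate block (0.0506), day 0 replicate 1 left out (0.0663), day 7 replicate 1, 2 or 3 left out (0.178, 0.0952 and 0.117) and diabetic replicate 1, 2 or 3 left out (0.122, 0.124 and 0.115). The call of miR-451a was lost without day 7 replicate 1 (0.0857), with total-count scaling and with limma. The rest did not pass: log2 fold changes were 0.94 for miR-133a-3p, 0.53 for miR-205-5p, 0.41 for miR-143-3p, 0.39 for let-7b-5p, 0.29 for miR-203-3p, 0.18 for miR-200c-3p, miR-199a-3p and miR-17-5p, 0.08 for miR-31-5p and 0.07 for miR-1a-3p. They were -0.72 for miR-132-3p, -0.27 for miR-126a-3p, -0.21 for miR-210-3p, -0.12 for miR-206-3p and -0.08 for miR-146a-5p. miR-205-5p passed with the replicate block (0.54, adjusted p = 0.0490, edgeR) and without day 0 replicate 1 (0.0140), let-7b-5p without diabetic replicate 3 (0.0363), miR-132-3p without diabetic replicate 1 (0.0432), and miR-133a-3p without day 7 replicate 3 (0.0457) or diabetic replicate 1 (0.0182). In all, miR-205-5p passed in 11 of 22 alternatives, miR-133a-3p in 6, let-7b-5p in 4 and miR-132-3p in 1. With these, 9 of the miRNAs listed as not passing here passed in at least 1 alternative.

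Against day 7, 5 of 7 myeloid and lymphoid miRNAs were lower in the diabetic group (5 adjusted over the list alone, median -1.30, camera adjusted p = 1.24e-05), with miR-142a-5p at 411 ± 46.2 CPM. Of 12 inflammation-induced miRNAs 6 were lower (9 adjusted over the list alone, median -0.87, adjusted p = 1.36e-05), including miR-146b-5p (-1.27 ± 0.19), whose call was lost with total-count scaling (0.0779). Of 17 keratinocyte and epithelial miRNAs 8 were higher (12 adjusted over the list alone, median 0.71, adjusted p = 6.15e-06), among them miR-200a-3p (0.95 ± 0.18) and miR-182-5p (0.84 ± 0.13). Of 4 miR-34 miRNAs 3 were lower (3 adjusted over the list alone, adjusted p = 0.0117) and of 7 erythroid miRNAs 3 were lower (6 adjusted over the list alone, adjusted p = 0.0439). Here too, list members that share a hairpin or cluster are not separate loci. With an estimated correlation the adjusted p of these lists, in the order given, was 0.148, 0.148, 0.160, 0.524 and 0.546. With total-count scaling their medians were -0.66, -0.20, 1.39, -1.45 and -0.07. By fry, 7 lists moved, the other two being the melanocyte and diabetic-wound lists (adjusted p = 0.0295 and 0.0418), and its mixed test called 10. The erythroid call ended without opposite-strand rows (0.130), with total-count scaling (0.121), with a CPM of at least 10 (0.0521), without day 7 replicate 1 (0.101) and without diabetic replicate 1 (0.0861), and the miR-34 call with a CPM of at least 10 (0.433) and without diabetic replicate 3 (0.0510). The other 13 lists had camera adjusted p-values from 0.218 to 0.854. The adipocyte list had a positive median (0.21) and a negative mean (-0.32), and the Dlk1-Dio3 list a median of -0.07 with an upward camera direction. Other splits of these 6 libraries called up to 7 lists, against 5 for the real split.

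In all, 89 of 447 miRNAs differed between the diabetic group and day 7, 35 higher and 54 lower (edgeR, adjusted p under 0.05), and 38.3% had ranges that did not overlap, against 10% by chance. Total-count scaling gave 174 higher and 24 lower and upper-quartile scaling 45 higher and 41 lower, with the median log2 fold change at 0.61 and 0.08 instead of -0.02. limma on TPM gave 170 higher and 24 lower. The count was 49 without day 7 replicate 1, 59 without day 7 replicate 2 and 52 without diabetic replicate 2. Without the 3 libraries numbered 2 it was 5: miR-335-3p, miR-223-3p, miR-223-5p, miR-21a-3p and miR-21a-5p.

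**Figure D3:**
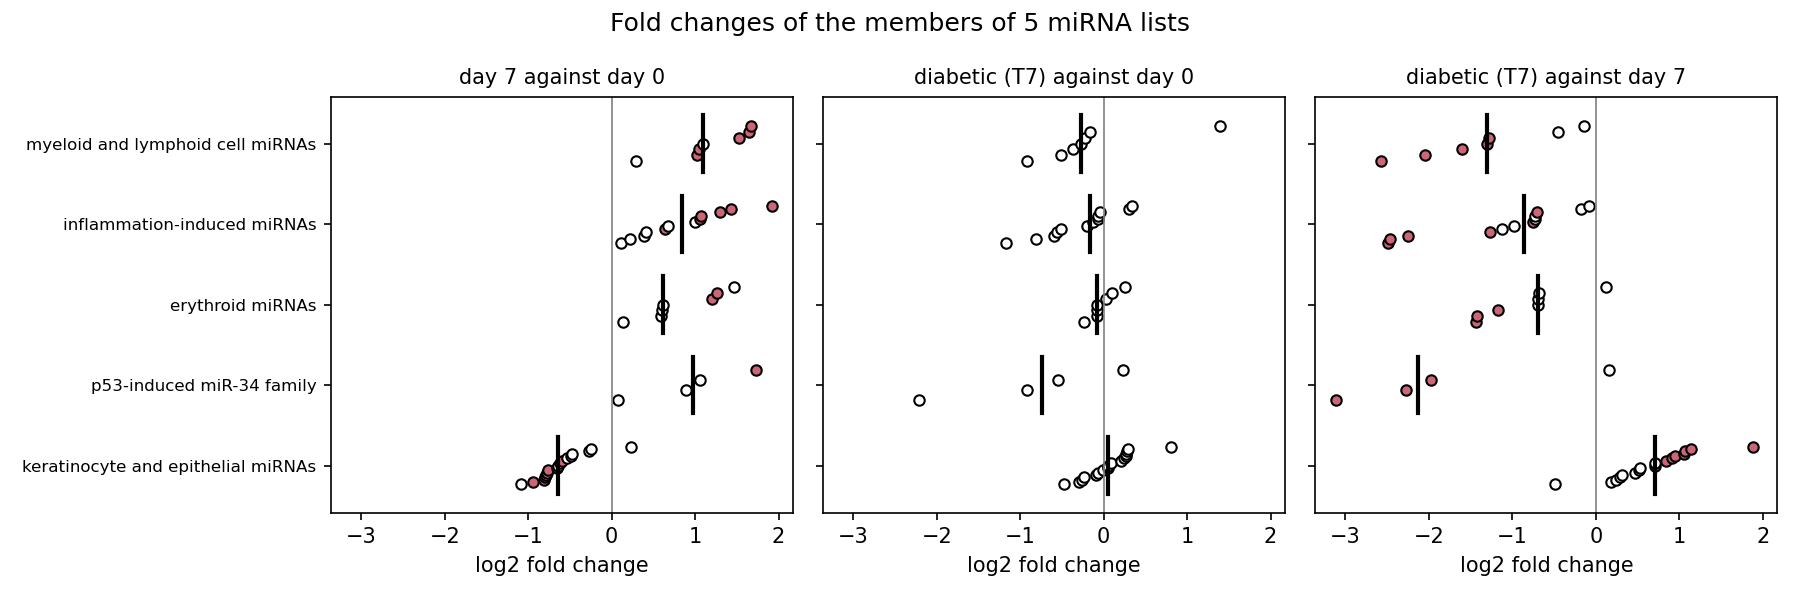
Log2 fold changes of the tested members of 5 miRNA lists in the 3 comparisons, on a common axis. Each point is a miRNA, filled where its edgeR adjusted p was under 0.05, and the black bar is the list's median. The myeloid and lymphoid median was 1.09 for day 7 against day 0, -0.27 for diabetic against day 0 and -1.30 for diabetic against day 7.

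The changes at day 7 and in the diabetic group against day 0 had 0 calls in common, since the latter had none by edgeR (40 at an unadjusted p under 0.05). With 0 calls in 1 comparison the overlap had to be 0. The 0 in 20 simulations of unchanged groups and the 0 of independent lists therefore test nothing here. The overlap was 2 with DESeq2, 1 with limma, 1 with the replicate block, and 1 without day 0 replicate 1 or without day 7 replicate 3. Of the 57 miRNAs changed at day 7, 49 differed in the opposite direction in the diabetic group against day 7, 33 of them higher and 16 lower at day 7. Independent lists of these sizes would share 5.99, and simulations with no effect shared 0. The overlap was 120 with total-count scaling, 122 with limma, 28 with total counts without miR-21a-5p, 27 with an absolute log2 fold change of at least 1, 25 without day 0 replicate 2, 21 without day 0 replicate 3, 15 without day 7 replicate 1, 21 without day 7 replicate 2, 30 without diabetic replicate 2 and 1 without the libraries numbered 2. Both comparisons use the 3 day 7 libraries. The value for independent lists leaves out that sharing and the simulated one leaves out the effects. Neither can therefore serve as a measure of chance here. In 1 fit, the change of diabetic against day 7 is that of diabetic against day 0 minus that of day 7 against day 0. With 0 calls in the diabetic group against day 0, an overlap in opposite directions follows largely from the design. The overlap of 49 is thus not a separate result.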

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

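The alternatives that dropped opposite-strand partner rows, miR-21a-5p, or the libraries numbered 2 were chosen after seeing the data. For the miRNAs that the naming rule gives, with up to 4 passing members of each list (42, 20 and 57), none changed direction while called, in 919 alternative values for day 7 against day 0, 435 for diabetic against day 0 and 1244 for diabetic against day 7. Without a call the sign changed in 14, 38 and 27 of these values. Calls were lost in 126, 0 and 177 and gained in 24, 2 and 32. miRNAs named after their values were seen, such as miR-342-3p in diabetic against day 0, are not among these. Of the 28 called among these for day 7 against day 0, 1 (miR-335-3p) passed in every alternative that tested it, and 5 of 42 did for diabetic against day 7.

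The number of changed miRNAs at day 7 against day 0 (57) was 133 with total counts only, 139 with limma on log2(TPM + 1), 33 with an absolute log2 fold change of at least 1, 35 with total counts without miR-21a-5p and 1 without the libraries numbered 2, and 19 to 68 with each replicate left out. For diabetic against day 7 (89) it was 198 with total counts only, 194 with limma, 5 without the libraries numbered 2, and 49 to 101 with each replicate left out. For diabetic against day 0 (0) it was 8 with DESeq2, 10 without the low-count filter, 1 with total counts, upper-quartile factors, limma, a CPM of at least 10 in 3 samples, the replicate block, the 5 most abundant miRNAs left out or the opposite-strand rows left out, and 0 to 2 with each replicate left out. Leaving out the libraries numbered 2 leaves 2 per group, so fewer samples enter the fit. limma on TPM shares the total-count scaling. For the other changes the cause was not tested.

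The overlap of day 7 and diabetic changes against day 0 (0) was 3 without the low-count filter, 2 with DESeq2, and 1 with total counts, upper-quartile factors, limma, a CPM of at least 10, the replicate block, the 5 most abundant miRNAs left out or the opposite-strand rows left out, and 0 to 1 with each replicate left out. With the estimated correlation 0 lists were called in any comparison. For diabetic against day 0 (3 lists), fry called 0 and the CPM filter 1, and for diabetic against day 7 (5 lists) the CPM filter called 3. The difference in the share of the 10 most abundant miRNAs was 9.60 points for day 7 minus day 0 and -12.1 for diabetic minus day 7. For the 5 most abundant it was 15.1 and -18.4, and for the 20 most abundant 6.37 and -7.79. With the replicate block the counts were 74, 1 and 93 changed miRNAs. Among the counts of changed miRNAs and their overlap, the block moved 2 results by more than 1.5 times, both from 0 to 1. Of the miRNAs whose test is given in the text it changed the calls of miR-206-3p at day 7 against day 0, miR-342-3p in diabetic against day 0, and miR-155-5p and miR-205-5p in diabetic against day 7, and within the cluster of miR-141 that of miR-141-3p at day 7 against day 0. It ended no list call.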

Other observations

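The scan of genomic clusters and its blocked fit, the overlap with the diabetic group against day 7, and the tests of strand, of miR-21a-5p and of miR-122-5p were chosen after the results were seen. The counts over other splits of the samples were planned. Hairpins within 10 kb of each other formed 33 clusters with at least 3 tested miRNAs. By camera 9 of them moved at day 7 against day 0, 4 up and 5 down, and 0 did with an estimated correlation (lowest adjusted p = 0.378). In the intron of Sfmbt2, which holds a rodent cluster of repeated miR-466, miR-467 and miR-669 hairpins, 6 of 13 miRNAs rose and none fell, with a median log2 fold change of 1.28 (camera adjusted p = 7.43e-06, and adjusted p = 0.378 with an estimated correlation). These rows share sequence, so their reads cannot be assigned to single members with certainty. Among them miR-467a-3p and miR-467d-3p held equal counts in every library, as did miR-467a-5p and miR-467b-5p. The values of each such pair thus entered the count, the median and camera more than once. In the intron of Clcn5, 3 of 7 rose (median 0.67, adjusted p = 0.0302, and 0.509 with an estimated correlation), the most abundant being miR-532-5p, at 1093 ± 74.2 CPM at day 0 and 2041 ± 366 CPM at day 7. miR-501-3p had a larger change (2.63-fold). In the diabetic group against day 7 the Sfmbt2 cluster had 5 lower members of 13 (adjusted p = 0.00297, and 0.435 with an estimated correlation).

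The clusters that fell at day 7 include 2 epithelial clusters of hairpins: miR-182, miR-183 and miR-96 (2 of 3 lower, median -0.79, camera adjusted p = 0.00234) and miR-200a, miR-200b and miR-429 (3 of 5 lower, median -0.66, adjusted p = 0.00234). The miR-203 rows fell in 3 of 4 (median -0.75, camera adjusted p = 0.0103). The row that did not pass, miR-203-3p (-0.24, adjusted p = 0.463, edgeR), held 1950069 counts over all libraries. The rows that fell held 118851 (miR-203b-5p), 2489 (miR-203-5p) and 2203 (miR-203b-3p), and the miR-203b hairpin lies on the opposite strand of miR-203. The cluster of miR-141 and miR-200c did not pass (0 of 3 lower, median -0.65, camera adjusted p = 0.107). With the replicate number as a block, 1 of these 3 was lower, miR-141-3p (-0.68, adjusted p = 0.0286, edgeR), and the cluster's adjusted p was 0.0978. The miR-181c and miR-181d cluster fell in 3 of 3 rows (median -0.79, adjusted p = 0.0148). With an estimated correlation the adjusted p was 0.378 for the first and 0.400 for the other clusters. In the diabetic group against day 0, 3 clusters moved by camera, 2 up and 1 down, and 0 did with an estimated correlation. The 1 that was lower was that of miR-34b and miR-34c (3 miRNAs, median -0.92, camera adjusted p = 0.00150, and 0.833 with an estimated correlation). It had 0 members past the single test. Its 3 miRNAs are all in the miR-34 list given above, so this is not a separate result. Of them, miR-34b-3p and miR-34c-3p averaged 5.65 and 2.90 CPM over the diabetic and day 7 libraries. In the comparisons given, the medians of the clusters named here kept their sign under TMM, RLE, upper-quartile and total-count scaling. Apart from those the rule for named miRNAs gives, miRNAs named here were chosen after their values were seen.

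The counts of calls were set against other splits of the same 6 libraries. For day 7 against day 0, the real split gave 57 changed miRNAs and the highest of the others gave 0. For the diabetic group against day 7 the values were 89 and 0, and for the diabetic group against day 0 they were 0 and 0. The real split was thus matched in 1, 1 and 10 of 10 splits. Each other split put libraries of both groups on either side, so a difference between the groups would add to its spread. Its 0 calls therefore give no rate of false calls. For the camera lists, the real splits called 4, 3 and 5 lists and the highest others called 8, 4 and 7, for day 7 against day 0, diabetic against day 0 and diabetic against day 7. As many lists were called in 6, 4 and 3 of the 10 splits. With 10 splits a share under 0.05 cannot be reached. Among the 4 splits that part all 3 same-numbered pairs, the others also called 0 miRNAs and up to 8, 4 and 7 lists.

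Pairs of rows that were equal within 5% in all 9 libraries stood out, such as miR-1a-3p and miR-1b-5p. Of the 15 pairs, 12 have hairpins on opposite strands of the same locus, which for these pairs is consistent with counting that did not use strand. Separate transcripts from both strands would differ by counting noise, yet in 9 of 11 such pairs with at least 1000 counts the chi-square of the difference was under 0.5 per degree of freedom. The pairs were picked for agreeing within 5%, which at low counts itself keeps the chi-square small, so a value under 0.5 in a shallow pair does not decide this. In the deep pairs miR-1a-3p with miR-1b-5p and miR-24-3p with miR-3074-5p the value was 0.119 and 0.0157. There the 5% tolerance is wider than counting noise. For these deep pairs the values argue against separate transcripts as the source of the equal rows. Some shallower pairs agreed far more closely than the 5% tolerance requires. miR-142a-3p with miR-142b, miR-122-5p with miR-122b-3p and miR-3065-5p with miR-338-3p held the same count in every library. miR-126a-5p and miR-126b-3p held 21770 and 21769 counts in all. For these pairs too the values argue against separate transcripts, and for the other pairs the question stays open. Among all 20 pairs of rows from overlapping opposite-strand hairpins with at least 1000 counts together, totals were within 5% in 10 and more than 2-fold apart in 8, such as miR-126a-3p (245374) and miR-126b-5p (822), and these stay open, since positions of mature sequences were not compared.

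With total-count scaling more miRNAs were lower than higher at day 7 (117 against 16), with a median log2 fold change of -0.46. A candidate explanation is the share of counts taken by miR-21a-5p. With miR-21a-5p left out of the totals the median was 0.11, past 0 but just outside the bound of 0.1 set for this explanation, so the test does not settle it by that bound. The number of lower calls was then 7, beside 28 higher, so the excess of lower calls was gone without miR-21a-5p. A true fall of most miRNAs in absolute amount stays open, as no spike-in was used here.

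miR-122-5p, a miRNA of liver, had counts of 16, 9 and 17 in the libraries numbered 2 and between 291 and 420 in the others, and depth does not account for it, since the library numbered 2 was neither the deepest nor the shallowest in 2 of 3 groups. Shared handling of same-numbered libraries is a possible explanation: without miR-122-5p and its partner row, the real numbering had the highest mean correlation of deviations of 36 arrangements (matched by 1, itself), at 0.170 against 0.147 for the next. That mean does not single out the libraries numbered 2, whose pairs had 0.0153, 0.176 and 0.151, against 0.0749 to 0.360 for the other numbers. The libraries numbered 3 were the shallowest of each group, and whether depth adds to the mean was not tested. RNA from liver cannot be told apart from shared handling, because miR-192-5p, which liver also holds, lay at 369 to 532 CPM in all libraries, above any miR-122-5p level, which hides a small addition. The miR-192-5p level was at least as high in the library numbered 2 as in both others in 0 of 3 groups and lowest there in 3 of 3. Liver RNA in the other libraries would give that direction, but with a small addition hidden it is no evidence for liver RNA. No biological explanation was tested, since the labels do not say what the numbers stand for.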
